A study of Synechocystis sp. PCC 6803 with 19 samples.

How the data were processed

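Total RNA of 19 cultures of Synechocystis sp. PCC 6803 was hybridized to one-colour Agilent arrays after labelling 7 µg with Cy3, per the labels' protocols. The series design gives 3 to 4 independent experiments per strain, grown at 32 °C and a photon flux of 40 µmol per square metre and second and harvested as 40 mL at an A730 of 1. The CS group had 4 arrays and ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE 3 each, with groups and replicate numbers taken from the sample titles. By their titles, the CS, ΔsigBCDE and ΔsigCDE arrays were re-analyses of earlier arrays. The study's title names acclimation to oxidative stress, and the samples used here were unstressed.

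The deposited scanner files hold processed signal intensity per spot (gProcessedSignal), written by Agilent Feature Extraction, 10.7.3.1 per the file headers and 10.7.3 per the submitters' processing notes, together with spot flags for background, saturation and outliers per the file headers. The authors' series table holds deposited log2 values, 1 per gene, whose array medians lay between 10.01 and 10.06 and which correlated across 3264 genes at 0.996 to 0.999 with the log2 scanner values. The normalization behind it is not given in the sources used here. Each array held 15744 spots, 15208 of them for genes, in 8091 probes of 3264 genes (1 probe for 61 genes, 2 for 1611, 3 for 1560 and 4 for 32). No spot was saturated (0). Outlier spots, 0.418% of all, were left out. The 75th percentile of intensity ran from 1297 to 4975 over the arrays and 89.3 to 99.9% of spots were well above background. The number of arrays limits the precision.

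Log2 intensity minus the 75th percentile of its array was averaged over the spots of a probe and then over the probes of a gene. The 3259 genes with a probe well above background on every array of at least 1 group were tested, and 3083 were above background on all arrays. A linear model with a mean per strain was fitted to all arrays with limma 3.58.1 in R 4.3.3 (13 residual degrees of freedom, lmFit and eBayes), so that the strains shared an estimate of the spread. Input was read with the R packages jsonlite (2.0.0) and data.table (version 1.17.8). Each inactivation strain was compared with CS, each triple strain with ΔsigBCDE, and the 4 triple strains with each other in an F test, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. A gene counted as changed in all 5 strains when each of the 5 comparisons with CS passed with the same sign. Changes are log2 fold changes with the standard error of the model. Where a probe was not well above background on any array of a group, a fold is given as at least the value against the background threshold of that group's arrays.

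Lists of genes (25 lists, 364 genes, all measured) were fixed before the data were examined: group 2 sigma factors, RNA polymerase core and other sigma factors, ribosomal proteins, photosystem I, photosystem II, cytochrome b6f and soluble electron carriers, ATP synthase, NDH-1 core, phycobilisome, carbon fixation and carboxysome, inducible inorganic carbon uptake and flavodiiron proteins, antioxidant enzymes, high light inducible proteins and OCP photoprotection, carotenoid and tocopherol synthesis, chaperones and heat shock proteins, FtsH and Deg proteases, iron stress and iron uptake, nitrogen assimilation, sugar catabolism and glycogen, bidirectional hydrogenase, polyhydroxybutyrate synthesis, phosphate uptake, type IV pili and motility, glucosylglycerol synthesis and uptake, and chlorophyll, haem and bilin synthesis. They were tested over 9 comparisons (225 tests) with camera from limma at a preset correlation of 0.01, adjusted within each comparison. With an estimated correlation 4 of the 60 calls held: phosphate uptake in ΔsigBCD against CS and against ΔsigBCDE, and group 2 sigma factors in ΔsigBCD and ΔsigCDE against CS. The group 2 list holds the inactivated genes, so its calls against CS were set by design. fry, which asks whether a list's genes move on balance in a single direction and compares them with no other genes, gave 93 calls. Counts of members are given over all genes and adjusted over the list alone. Gene symbols come from these lists, and other genes carry the locus tags of the files. None (0) of the 3264 locus tags matched the reference table of 3347 genes, which was therefore not used for names.

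The rule for named genes was written before the data were examined. For each strain against CS it took all sigma factor genes, the 10 highest and 10 lowest changes among called genes whose arrays did not overlap with CS, and up to 4 called members with the largest change from each list with a list call or at least 2 called members, plus any member stated as not called. Against ΔsigBCDE it took the 5 highest, the 5 lowest and up to 3 called members per list. For all 5 strains and for the F test it took 10 genes each. Within this rule, genes whose calls held when single arrays were left out were preferred for the text, a choice made after the data were examined, and at most 4 genes without a symbol are named per comparison. sll0686 in ΔsigBCD and sll0685 in ΔsigBCDE and ΔsigCDE were named after their values were seen.

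Alternatives set before the data were examined were quantile normalization, median scaling, the authors' log2 values, normexp background correction (offset 50, on the median signal because the files hold no mean signal column), no filter on dim genes, only genes above background on all arrays, the brightest probe of a gene, the slide as a fixed or random block (estimated correlation 0.225), differences within slides, the replicate number as a block, only the strains compared, an intensity trend in eBayes, a change of at least 1 on the log2 scale, and leaving out each array. The scan session as a block and fits within each of the 2 sessions were chosen after seeing the data. Replicate numbers were taken to pair arrays where every pair's deviations from the strain means correlated at over 0.1. That held for ΔsigCDE against CS (0.499 to 0.542 over 3 pairs, each on a single slide) and ΔsigBDE against ΔsigBCDE (0.106 to 0.561 over 3 pairs, each on a single slide), and for no other comparison. For results shared between strains, unchanged strains were simulated against the same CS arrays.

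In simulated data for ΔsigBCDE against CS with 3259 genes, 8 unchanged genes were called. Of those changed by 0.5, 1 and 2 on the log2 scale, 27 of 67, 60 of 67 and 65 of 66 were. In the F test over 3259 genes, 178 of 200 raised by 1 in ΔsigBCE were called, with 11 false calls. For ΔsigBDE against CS 3 of 3 raised lists were called, with 0 false calls among 25. Lists of correlated genes were not simulated.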

Results

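Transcripts of the cyanobacterium Synechocystis sp. PCC 6803 were measured on 19 one-colour Agilent arrays. Group 2 sigma factors resemble the primary factor SigA, which directs RNA polymerase to promoters, but cells grow without them. The control strain (CS) had 4 arrays. ΔsigBCDE, which lacked all 4 group 2 factors, and 4 triple inactivation strains had 3 arrays each. Among the triple strains, ΔsigBCD retained SigE, ΔsigBCE SigD, ΔsigBDE SigC and ΔsigCDE SigB. The cells had grown unstressed at 32 °C in light of 40 µmol photons per square metre and second. The 75th percentile of the processed intensity ran from 1297 to 4975 over the arrays, and 89.3 to 99.9% of spots were well above background. The number of arrays limits the precision of each value. Across genes, which are not independent replicates, log2 values of arrays of the same strain correlated at 0.976 to 0.997 and those of different strains at 0.900 to 0.985. The arrays lay on 5 slides read in 2 scan sessions. Control array 4 was the only CS array in the session of ΔsigBCDE, ΔsigBCD and ΔsigBDE, and ΔsigCDE shared neither slide nor session with ΔsigBCDE.

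**Figure D1:**
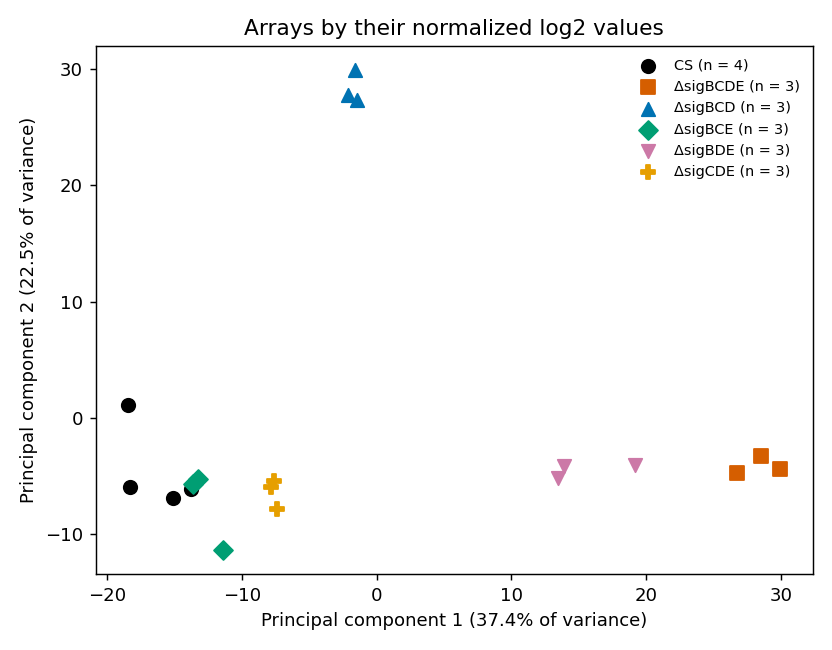
Arrays on the first and second principal component of the normalized log2 values (37.4% and 22.5% of the variance), 1 point per array, coloured by strain. ΔsigBCDE arrays lay at 26.7 to 29.9 and ΔsigBDE arrays at 13.5 to 19.2 on the first component, CS arrays at -18.4 to -13.7, and ΔsigBCD arrays at 27.3 to 29.9 on the second.

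The inactivated genes were read first, as a check of the strain labels. Averaged over all probes of a gene, every inactivated sigma gene was lower than in CS in the strain concerned (16 of 16). In ΔsigBCDE, sigB changed by -0.76 on the log2 scale (SE 0.19, limma adjusted p = 0.00220), sigC by -1.77 (SE 0.11, adjusted p = 2.89e-09), sigD by -3.82 (SE 0.32, adjusted p = 4.80e-08) and sigE by -2.37 (SE 0.15, adjusted p = 2.93e-09). In ΔsigBCD, sigB was at -1.01, sigC at -0.90 and sigD at -3.46 against CS, with adjusted p of 0.000552, 1.00e-05 and 2.87e-07. In ΔsigBCE, sigB was at -0.64, sigC at -0.53 and sigE at -3.60 (0.0321, 0.00472 and 5.41e-11). In ΔsigBDE, sigB was at -0.68, sigD at -3.94 and sigE at -2.12 (0.00776, 1.15e-07 and 5.16e-08). In ΔsigCDE, sigC was at -0.46, sigD at -1.65 and sigE at -3.21 (0.0142, 0.00258 and 3.55e-10).

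Retained factors were not all at the control level. The retained sigB of ΔsigCDE was at 0.00 (adjusted p = 0.998) and the retained sigD of ΔsigBCE at 0.67 (adjusted p = 0.196), neither called, though the brightest sigD probe was (0.74, adjusted p = 0.0300). By contrast, the retained sigC of ΔsigBDE fell by 0.62 (adjusted p = 0.000322, and 0.0751 with normexp) and the retained sigE of ΔsigBCD by 1.11 (adjusted p = 2.93e-05). The first exceeded the fall of the inactivated sigC in ΔsigBCE and ΔsigCDE and the second that of sigB in every strain without it, so the averages did not separate inactivated from retained genes. The list of the 4 group 2 genes holds the inactivated genes themselves, so its fall was set by design and checks the labels only. It was lower in all 5 strains, with adjusted p of 0.00245, 0.000517, 0.00404, 0.000858 and 0.000154 for ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE and medians of -2.07, -1.06, -0.58, -1.40 and -1.05. With an estimated correlation these p were 0.0806, 0.0138, 0.0522, 0.0583 and 0.0173. The medians with the slide as a block were -2.05, -1.05, -0.55, -1.39 and -1.07 and with the scan session -2.01, -1.07, -0.62, -1.41 and -1.03, and within single slides and sessions they ran from -2.15 to -1.99, -1.06 to -1.01, -0.67 to -0.42, -1.33 to -1.32 and -1.18 to -0.97. Over the list alone, 4, 4, 3, 4 and 3 genes were called, as over all genes.

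The probes of each sigma gene did not move together, and the sources used here do not say which part of each gene was replaced, so a probe outside that part checks nothing. The sigB probe at position 688 stood at 1.66 ± 0.08 (mean and SD, n = 4) in CS and at 1.61 ± 0.12 (n = 3) in ΔsigCDE, which retained sigB, against -1.24 ± 0.29 to 0.01 ± 0.26 in the 4 strains without it, while the probes at 206 and 252 differed little. The sigC probe at 343 was not well above background in ΔsigBCDE, at least 37.2-fold lower than in CS, and was above background in the 3 triple strains without SigC. The sigC probe at 918 went the other way in ΔsigBCDE, at -0.04 ± 0.14 against -2.28 ± 0.12 in CS. In ΔsigBDE it stood near CS, at -2.33 ± 0.26, against -2.61 ± 0.11, -2.97 ± 0.03 and -2.88 ± 0.21 in ΔsigBCD, ΔsigBCE and ΔsigCDE. The sigD probe at 699 was at least 57.1-fold lower in ΔsigBDE and stood at -6.06 ± 0.47 in ΔsigBCD and -6.54 ± 1.79 in ΔsigBCDE, against -0.26 ± 0.34 in CS. In ΔsigCDE, which also lacks SigD, it stood at -2.85 ± 0.20, well above background on 3 of 3 arrays. The sigD probe at 1 was not lower in any strain. The sigE probe at 950 stood at 0.28 ± 0.33 in CS and -0.93 ± 0.12 in ΔsigBCD, which retained sigE, against -5.86 ± 0.72 in ΔsigBCE, -5.54 ± 0.13 in ΔsigCDE, -2.66 ± 0.50 in ΔsigBCDE and -2.83 ± 0.14 in ΔsigBDE. In ΔsigBCDE and ΔsigBDE, which lack SigE, it was still well above background on 3 of 3 arrays each. Single arrays decided some of these calls. The sigB call in ΔsigBCE ended without CS replicate 1 (adjusted p = 0.0856), 2 (0.0702) or 4 (0.0674) or without ΔsigBCE replicate 1 (0.112) or 3 (0.107), and with the slide as a block (0.133) or median scaling (0.0651). The sigB call in ΔsigBDE ended without ΔsigBDE replicate 1 (0.0558) and the sigC call in ΔsigCDE without ΔsigCDE replicate 1 (0.0530) or 2 (0.0633) and with normexp (0.0819). Fits within a single scan session ended the sigB and sigC calls in ΔsigBCE (0.0617 and 0.119 in the first, 0.355 and 0.132 in the second) and the sigB call in ΔsigBDE (0.0902). With the brightest probe of each gene, 6 of the 16 were called lower and the group 2 list was called in no strain.

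**Figure D2:**
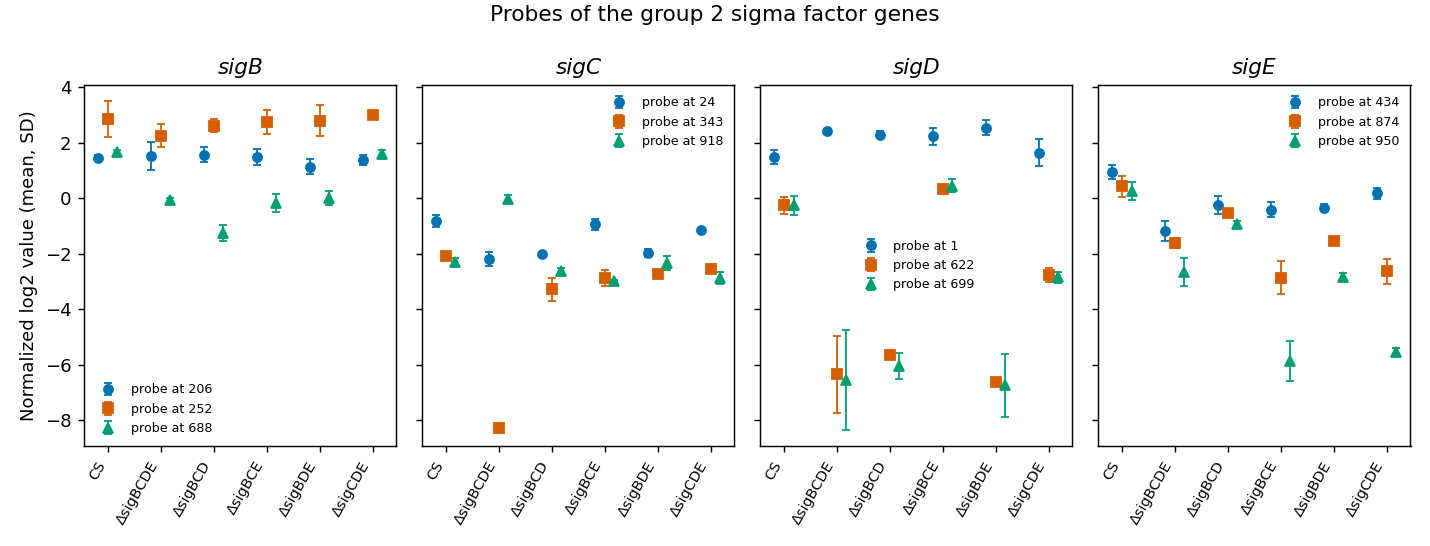
Normalized log2 values of the 3 probes of each group 2 sigma factor gene by strain, as means with SD bars (n = 4 for CS, n = 3 for the other strains), labelled by the probe's start in the gene. The sigB probe at 688 lay at 1.66 in CS and 1.61 in ΔsigCDE and at or below 0.01 in the 4 strains without sigB.

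The gene of the primary factor, sigA, fell by 2.56 in ΔsigBCDE (SE 0.24, adjusted p = 1.53e-07), by 1.74 in ΔsigBCD (SE 0.24, adjusted p = 2.46e-05) and by 1.50 in ΔsigBDE (SE 0.24, adjusted p = 8.69e-05). It was not called in ΔsigCDE (-0.34, adjusted p = 0.425), nor in ΔsigBCE (-0.56, adjusted p = 0.137), where it was called after quantile normalization (-0.68, adjusted p = 0.0283), with the authors' values (-0.72, 0.0127), with the scan session as a block (-0.82, 0.0165) and within the first session (-1.21, 0.0235). sigI rose by 2.35 in ΔsigBCD (adjusted p = 7.22e-09) and by 1.15 in ΔsigCDE (adjusted p = 0.000168). sigI is sll0687, and the locus tag before it, sll0686, rose by 3.02 (adjusted p = 5.75e-09) and 1.46 (adjusted p = 0.000167) in the same strains, while sll0685 was not well above background in ΔsigBCD, rose by 1.60 in ΔsigCDE (adjusted p = 6.16e-05) and fell by 2.08 in ΔsigBCDE (adjusted p = 3.03e-07). Whether a change at this locus in ΔsigBCD underlies its sigI value was not tested. In ΔsigBDE sigI stood at 0.47 (adjusted p = 0.0299), a call that ended without CS replicate 3 or 4 or ΔsigBDE replicate 1 or 2 (adjusted p = 0.0903, 0.0612, 0.0776 and 0.0986) and with the slide or the scan session as a block (0.105 and 0.111) and within the second session (0.151). It was not called in ΔsigBCDE (-0.19, adjusted p = 0.326) or ΔsigBCE (-0.11, adjusted p = 0.729). With the brightest probe the calls of sigI (0.477) and sll0686 (0.0696) in ΔsigCDE ended.

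sigF, for a factor of motility genes, fell by 0.57 in ΔsigBCDE (SE 0.11, adjusted p = 0.000205). In ΔsigBCD it was at -0.34 (adjusted p = 0.0221), a call that ended with normexp (0.0856), with the slide as a block (0.270), with the scan session as a block (0.293), without CS replicate 3 (0.0646), without ΔsigBCD replicate 1 (0.0632) and without ΔsigBCD replicate 3 (0.0733). Within the second session it was not called either (adjusted p = 0.392). In ΔsigBCE, ΔsigBDE and ΔsigCDE it was at 0.17, -0.20 and 0.13, not called, though with its brightest probe it was called in ΔsigBDE (-0.41, adjusted p = 0.0148). sigH was at 0.96 in ΔsigBCDE (adjusted p = 0.0361), a call that ended with normexp (0.0516), with its brightest probe (0.0859), with the slide as a block (0.184), with the scan session as a block (0.157), without CS replicate 2 (0.0641), without CS replicate 3 (0.0518), without CS replicate 4 (0.110), without ΔsigBCDE replicate 1 (0.0586), without ΔsigBCDE replicate 2 (0.0939) and without ΔsigBCDE replicate 3 (0.0776). In ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE sigH was at 0.48, 0.86, -0.01 and 0.39, not called, though without ΔsigBCE replicate 1 it was called in ΔsigBCE (1.29, adjusted p = 0.0345). sigG was called in no strain, at 0.01, 0.33, 0.35, -0.03 and 0.43 in ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE.

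The absence of all group 2 factors in unstressed cells was read from ΔsigBCDE against CS. gnd, opcA and tal, of the pentose phosphate pathway that yields NADPH from stored sugar, fell. gnd, for phosphogluconate dehydrogenase, stood at -2.15 ± 0.13 (SD, n = 3) against 0.85 ± 0.11 (n = 4) in CS, a log2 fold change of -3.00 (SE 0.11, adjusted p = 6.63e-12). opcA, for an activator of glucose phosphate dehydrogenase, changed by -3.04 (SE 0.22) and tal, for transaldolase, by -2.97 (SE 0.15). Glycogen phosphorylase gene glgP1 (-1.56) and the hydrogenase genes hoxY (-1.59) and hoxH (-1.37) were lower too. In the opposite direction, atpF (1.81, SE 0.16) and atpD (1.56, SE 0.16) of the ATP synthase, the carboxysome shell genes ccmL (1.54), ccmM (1.52) and ccmK2 (1.41) and the ribosomal protein genes rpl1 (1.51) and rpl3 (1.51) rose. Among genes named only by locus tag, ssr2016 (4.71) and slr0364 (3.85) rose most and slr0376 (-4.64) and slr1770 (-3.76) fell.

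hliA (1.91) and hliB (1.93), for small proteins made in high light, and nblA1 (1.78) and nblA2 (1.75), for phycobilisome degradation, rose, as did the pilin genes pilA1 (2.04), pilA2 (2.11) and pilA4 (2.31) and the protease gene htrA (1.99). Of the antioxidant genes, the peroxidase gene gpx1 (-1.63), the thioredoxin gene trxQ (-1.49) and the peroxiredoxin gene prxQ2 (-1.29) fell, while perR, for a repressor of peroxide responses, rose by 1.18. sodB, for superoxide dismutase, was not called (0.15, adjusted p = 0.280). In the antioxidant list 3 of 16 rose and 7 fell, 3 and 7 adjusted over the list alone, and the list was not called (median -0.03, adjusted p = 0.369, adjusted p = 0.832 with an estimated correlation). The tocopherol methyltransferase gene vte4 (-1.73) and chlL (-1.66), of light-independent chlorophyll synthesis, fell, and petJ, for a soluble cytochrome, rose by 1.65.

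Among ribosomal protein genes 35 of 53 rose and 2 fell, 35 and 2 adjusted over the list alone (median 0.81, adjusted p = 3.01e-06, adjusted p = 0.580 with an estimated correlation). Within the ATP synthase genes 10 of 10 rose, 10 adjusted over the list alone (median 1.22, adjusted p = 7.21e-06, adjusted p = 0.209 with an estimated correlation). Among carbon fixation and carboxysome genes 9 of 14 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.79, adjusted p = 0.000384, adjusted p = 0.196 with an estimated correlation). Within the phosphate uptake genes 6 of 12 rose, 6 adjusted over the list alone (median 0.53, adjusted p = 0.0137, adjusted p = 0.580 with an estimated correlation). Within the sugar catabolism and glycogen genes 3 of 17 rose and 10 fell, 3 and 12 adjusted over the list alone (median -0.54, adjusted p = 0.00863, adjusted p = 0.258 with an estimated correlation). All hydrogenase genes fell (5 of 5, 5 adjusted over the list alone, median -1.37, adjusted p = 0.0137, adjusted p = 0.454 with an estimated correlation). Of the high light inducible genes 3 of 6 rose, 3 adjusted over the list alone, with no call for the list (median 0.40, adjusted p = 0.0963, adjusted p = 0.454 with an estimated correlation). Fits with a slide block gave medians of 1.01 for ribosomal proteins, 1.00 for the ATP synthase, 0.69 for carbon fixation, -0.54 for sugar catabolism, -1.18 for the hydrogenase and 0.48 for phosphate uptake. With the scan session instead they were 1.07, 1.07, 0.71, -0.51, -1.01 and 0.55 in that order. The phosphate uptake list was not called with the slide as a block (adjusted p = 0.0784), and the sugar catabolism list not with the brightest probe of each gene (0.263). Within the slide and the session that held both strains the medians ran from 1.04 to 1.22, 1.14 to 1.28, 0.66 to 0.71, -0.75 to -0.57, -1.08 to -1.05 and 0.19 to 0.54. Photosystem I, not called here (1 of 12 rose and 5 fell, 1 and 5 adjusted over the list alone, median -0.54, adjusted p = 0.227, adjusted p = 0.832 with an estimated correlation), was lower with the slide (adjusted p = 0.00635) or the scan session as a block (0.00317), and so was NDH-1 (1 of 15 rose and 9 fell, 1 and 10 adjusted over the list alone, median -0.48, adjusted p = 0.0675, adjusted p = 0.698 with an estimated correlation) with adjusted p of 0.00544 and 0.00234. 1829 of 3259 genes were called (867 higher, 962 lower), 637 of them by at least 1 on the log2 scale. With the slide as a block 1736 genes were called (868 higher, 868 lower) and with the scan session 1755 (924 higher, 831 lower), of which 1510 and 1494 were called with the same sign without a block. 1689 of the called genes had arrays of the 2 strains that did not overlap, which holds for 56.1% of all genes tested and 5.71% by chance.

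**Figure D3:**
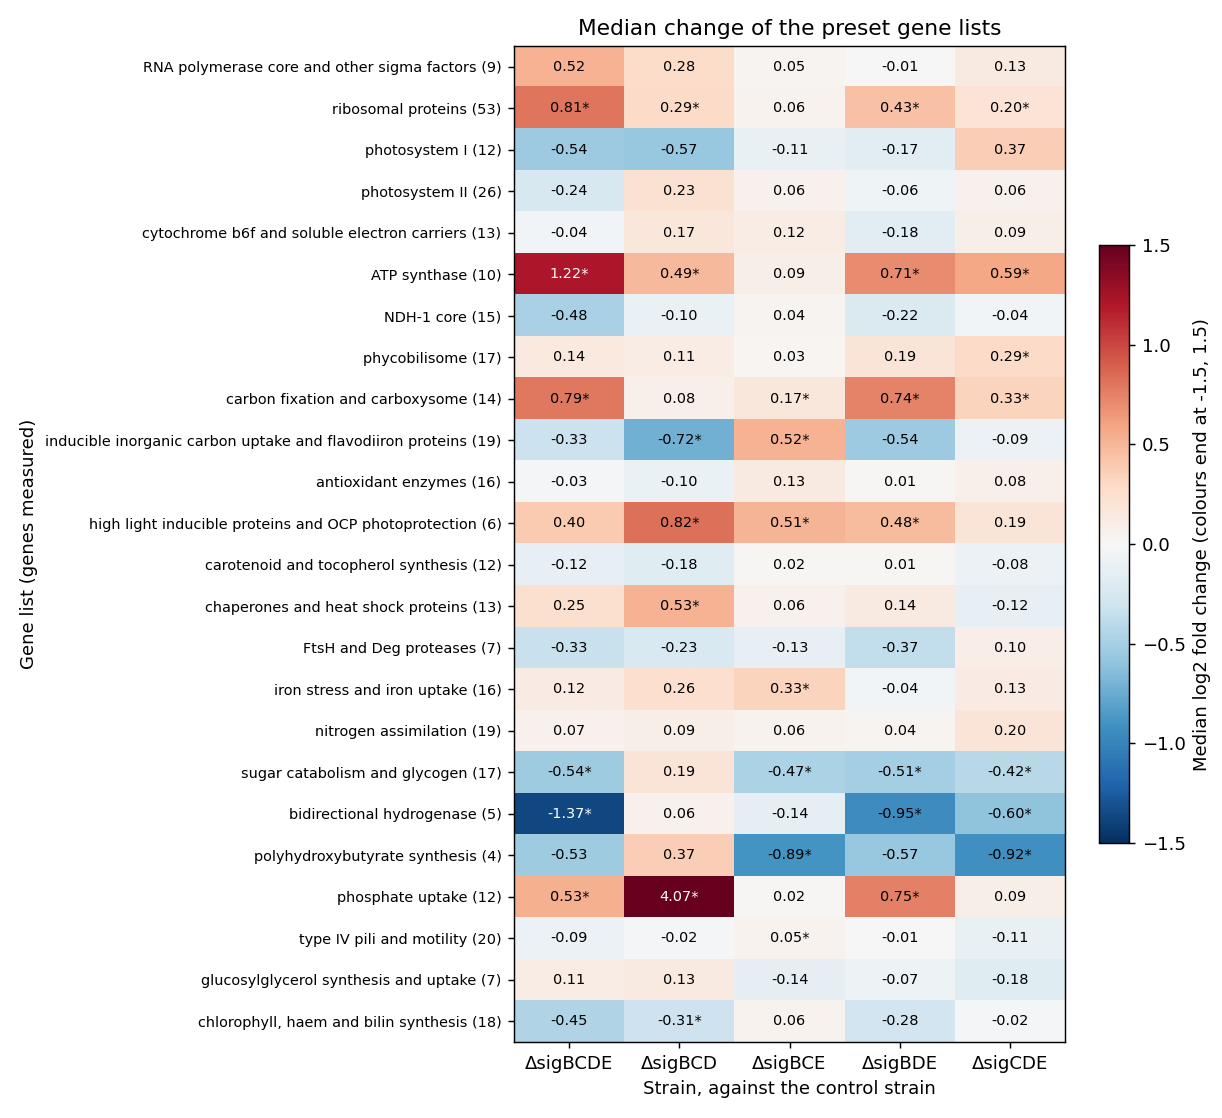
Median log2 fold change of 24 preset gene lists in each strain against CS (n = 3 against n = 4 arrays), with the number of genes measured in brackets; an asterisk marks an adjusted p under 0.05 in camera with the preset correlation, and colours end at -1.5 and 1.5. Phosphate uptake stood at 4.07 in ΔsigBCD, and the ATP synthase ran from 0.09 in ΔsigBCE to 1.22 in ΔsigBCDE.

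What was changed when only SigE remained was read from ΔsigBCD against CS. The phosphate uptake genes, which cells normally raise when phosphate runs short, had the highest median of all lists. pstS2, for a phosphate-binding protein, stood at 3.29 ± 0.04 (SD, n = 3) against -3.47 ± 0.36 (n = 4) in CS, a log2 fold change of 6.77 (SE 0.36, adjusted p = 2.02e-10). phoA, for alkaline phosphatase, rose by 6.70 (SE 0.39), pstC2 by 6.66 (SE 0.36) and pstA2 by 5.52 (SE 0.21). Of the phosphate uptake genes, 12 of 12 rose, 12 adjusted over the list alone (median 4.07, adjusted p = 3.02e-26, adjusted p = 0.00519 with an estimated correlation). sll0685, the locus tag next in number after the phosphate transporter gene pstB1b, was not well above background in ΔsigBCD, at least 136-fold and 291-fold lower than in CS at its 2 probes.

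The pentose phosphate genes gnd and tal rose in this strain, gnd by 1.32 (SE 0.11, adjusted p = 1.09e-07) and tal by 0.93 (SE 0.15, adjusted p = 0.000179). Against ΔsigBCDE these 2 genes differed by 4.32 (adjusted p = 4.27e-14) and 3.90 (adjusted p = 9.95e-12). In the sugar catabolism list 7 of 17 rose and 1 fell, 7 and 3 adjusted over the list alone, with no call for the list (median 0.19, adjusted p = 0.0859, adjusted p = 0.510 with an estimated correlation). ocp, for the orange carotenoid protein that quenches excess light, rose by 2.13 (SE 0.27) and its recovery protein gene frp by 1.15 (SE 0.15). The heat shock gene hspA (1.17, adjusted p = 0.000363, and 0.0583 within the second session), the protease gene htrA (2.53), sodB (0.94) and the pilin genes pilA1 (2.50) and pilA2 (2.87) rose as well. The bicarbonate transporter gene cmpA (-2.42, SE 0.49, adjusted p = 0.00129) and porB (-2.58, SE 0.60) of the same list fell, as did trxQ (-1.61), gpx1 (-1.43) and pilQ (-1.35).

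Of the high light inducible and photoprotection genes, 4 of 6 rose, 4 adjusted over the list alone (median 0.82, adjusted p = 0.00381, adjusted p = 0.122 with an estimated correlation). Of the ATP synthase genes, 7 of 10 rose, 7 adjusted over the list alone (median 0.49, adjusted p = 0.00122, adjusted p = 0.342 with an estimated correlation). Within the ribosomal protein genes 4 of 53 rose, 4 adjusted over the list alone (median 0.29, adjusted p = 0.000616, adjusted p = 0.758 with an estimated correlation). Among chaperone genes 9 of 13 rose and 1 fell, 10 and 3 adjusted over the list alone (median 0.53, adjusted p = 0.0216, adjusted p = 0.342 with an estimated correlation). Of the inorganic carbon uptake and flavodiiron genes, 1 of 19 rose and 12 fell, 1 and 14 adjusted over the list alone (median -0.72, adjusted p = 0.00384, adjusted p = 0.758 with an estimated correlation). Among chlorophyll, haem and bilin genes 6 of 18 fell, 6 adjusted over the list alone (median -0.31, adjusted p = 0.0193, adjusted p = 0.298 with an estimated correlation). The slide block gave medians of 3.96 for phosphate uptake, 0.50 for ribosomal proteins, 0.42 for the ATP synthase, 1.06 for high light inducible proteins, 0.51 for chaperones, -0.97 for carbon uptake and -0.42 for chlorophyll synthesis. A scan session block gave 4.08, 0.53, 0.46, 0.98, 0.50, -1.03 and -0.29 in that order. Within the slide and the session that held both strains the medians ran from 3.85 to 3.99, 0.20 to 0.60, 0.17 to 0.52, 0.94 to 1.02, 0.49 to 0.52, -1.11 to -0.94 and -0.32 to -0.25. Without ΔsigBCD replicate 1 the adjusted p of the ribosomal list was 0.0556, that of the carbon uptake list 0.0502 and that of the chaperone list 0.0556. Photosystem I (4 of 12 fell, 5 adjusted over the list alone, median -0.57, adjusted p = 0.168, adjusted p = 0.889 with an estimated correlation) was lower with the slide (adjusted p = 0.000243) or the scan session as a block (4.77e-05). 941 of 3259 genes were called (420 higher, 521 lower), 221 of them by at least 1, with 715 (332 higher, 383 lower) and 791 (408 higher, 383 lower) under the slide and the scan session as a block, of which 581 and 591 were among the same calls with the same sign. 876 of the called genes had arrays of the 2 strains that did not overlap, which holds for 37.3% of all genes tested and 5.71% by chance.

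**Figure D4:**
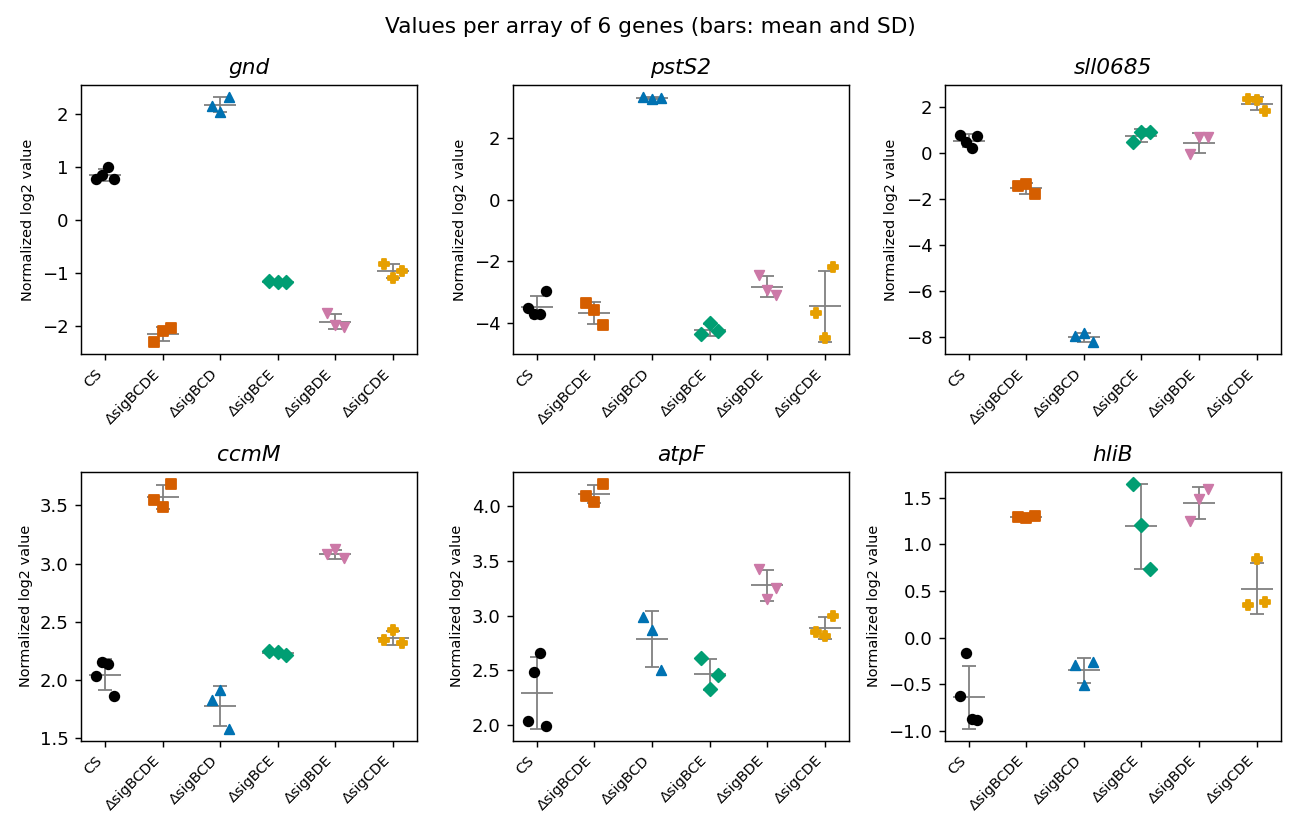
Normalized log2 values per array of gnd, pstS2, sll0685, ccmM, atpF and hliB by strain, with the mean and SD as bars (n = 4 for CS, n = 3 for the other strains). The pstS2 mean was 3.29 in ΔsigBCD against -3.47 in CS, and the gnd mean 2.17 in ΔsigBCD against -2.15 in ΔsigBCDE.

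What was changed when only SigD remained was read from ΔsigBCE against CS. The pentose phosphate genes tal (-2.12, SE 0.15, adjusted p = 7.22e-08), gnd (-2.02, SE 0.11) and opcA (-1.47, SE 0.22) fell. So did phaA (-1.18, adjusted p = 0.00225, and 0.159 for its brightest probe) and phaB (-0.96), of the synthesis of the storage polymer polyhydroxybutyrate. flv4, for a flavodiiron protein that takes electrons from photosystem II, rose by 1.98 (SE 0.45, adjusted p = 0.00662). Within the first scan session, with 1 ΔsigBCE array, it was at 0.97 (adjusted p = 0.404), not called, and within the second, with 1 CS array, at 2.52 (0.0221). hliB rose by 1.83 (SE 0.20), hliA by 1.15 and frp by 0.79, and the pilin genes pilA4 by 2.36, pilA2 by 1.35 and pilA1 by 1.17. The iron transporter gene futC was at 0.83 and petJ at 1.42, both higher. frp, at 0.58 within the first session, was not called there. The calls of pilA1 (adjusted p = 0.0663) and futC (0.0638) also ended within it, and those of phaA (0.205), pilA1 (0.244), pilA2 (0.0892) and futC (0.206) within the second. Among genes named by locus tag, slr0364 (2.75) and slr0366 (2.54) rose and ssl1533 (-1.75) fell.

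Of the sugar catabolism and glycogen genes, 9 of 17 fell, 3 higher and 10 lower adjusted over the list alone (median -0.47, adjusted p = 0.000170, adjusted p = 0.0522 with an estimated correlation). All polyhydroxybutyrate genes fell (4 of 4, 4 adjusted over the list alone, median -0.89, adjusted p = 0.000345, adjusted p = 0.0522 with an estimated correlation). Among high light inducible and photoprotection genes 3 of 6 rose, 3 adjusted over the list alone (median 0.51, adjusted p = 0.00404, adjusted p = 0.0911 with an estimated correlation). Among inorganic carbon uptake and flavodiiron genes 4 of 19 rose, 6 adjusted over the list alone (median 0.52, adjusted p = 0.00404, adjusted p = 0.778 with an estimated correlation). Within the iron stress and uptake genes 4 of 16 rose, 5 adjusted over the list alone (median 0.33, adjusted p = 0.0306, adjusted p = 0.588 with an estimated correlation). Within the carbon fixation and carboxysome genes 3 of 14 rose, 4 adjusted over the list alone (median 0.17, adjusted p = 0.0467, adjusted p = 0.588 with an estimated correlation). Within the pilus and motility genes 5 of 20 rose, 5 adjusted over the list alone (median 0.05, adjusted p = 0.0306, adjusted p = 0.750 with an estimated correlation). With the slide as a block, list medians were -0.54 for sugar catabolism, -1.18 for polyhydroxybutyrate, 0.61 for high light inducible proteins, 0.55 for carbon uptake, 0.34 for iron, 0.18 for carbon fixation and -0.06 for pili. The scan session as a block gave -0.48, -0.96, 0.57, 0.25, 0.41, 0.17 and 0.01 in that order. Within slides and sessions the medians ran from -0.50 to -0.32, -1.04 to -0.89, 0.50 to 0.73, 0.18 to 0.75, 0.25 to 0.53, 0.16 to 0.19 and -0.04 to 0.03, and the pilus list kept its sign in 1 of 3 batches.

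The carbon uptake, iron, carbon fixation and pilus calls of ΔsigBCE rested on single arrays. The adjusted p of the carbon uptake list was 0.0871 without CS replicate 3, 0.0554 without ΔsigBCE replicate 2 and 0.0624 without ΔsigBCE replicate 3, that of the iron list 0.0575 without CS replicate 1, 0.115 without CS replicate 3 and 0.121 without ΔsigBCE replicate 2, and that of the pilus list 0.0575 without CS replicate 1, 0.0742 without CS replicate 2, 0.0663 without CS replicate 3 and 0.218 without ΔsigBCE replicate 2, the last with the median below 0. For the carbon fixation list it was 0.0511 without CS replicate 1, 0.0567 without CS replicate 2, 0.156 without CS replicate 3, 0.156 without ΔsigBCE replicate 2, 0.310 without ΔsigBCE replicate 3, 0.0525 without ΔsigBDE replicate 1, 0.05004 without ΔsigBDE replicate 2 and 0.0506 without ΔsigBDE replicate 3. Other processing also ended calls, of carbon fixation with quantile normalization (0.113), median scaling (0.0777), the authors' values (0.0501), only genes above background on all arrays (0.0522) and the brightest probe of each gene (0.185), of iron with normexp (0.0566) and the brightest probe of each gene (0.306) and of pili with the brightest probe of each gene (0.157). With the slide as a block the p of the iron, carbon fixation and pilus lists were 0.113, 0.143 and 0.480, and with the scan session as a block those of the carbon uptake, iron, carbon fixation and pilus lists were 0.416, 0.259, 0.417 and 0.416. 410 of 3259 genes were called (195 higher, 215 lower), 73 of them by at least 1. With the slide as a block 356 genes were called (162 higher, 194 lower) and with the scan session 626 (349 higher, 277 lower), of which 277 and 359 were among the same calls. With normexp 104 were higher and 164 lower, so the balance of the 2 directions was not stable. 379 of the called genes had arrays of the 2 strains that did not overlap, which holds for 22.2% of all genes tested and 5.71% by chance.

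What was changed when only SigC remained was read from ΔsigBDE against CS. gnd fell by 2.77 (SE 0.11, adjusted p = 2.52e-11) and tal by 2.45 (SE 0.15), and the glycogen debranching gene glgX1 (-1.61) and hoxY (-1.15) were lower. The carboxysome genes ccmK4 (1.15), ccmK2 (1.08) and ccmM (1.03), atpF (0.98), rpl1 (1.03) and rpl3 (1.11) rose, and the phosphate-binding protein gene pstS1 rose by 1.07 (SE 0.16). hliB (2.08, SE 0.20) and hliA (1.91, SE 0.23) rose. Among antioxidant genes, perR (1.50) and the peroxiredoxin gene prxII (1.04, adjusted p = 0.000313, and 0.0842 within the second session) rose, and gpx1 (-1.55) and prxQ2 (-0.85) fell. vte4 fell by 1.75. Of genes named by locus tag, ssr2016 (3.83) and sll1634 (2.85) rose most and slr1770 (-2.52) and sll0426 (-2.38) fell.

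Of the ribosomal protein genes, 23 of 53 rose, 23 adjusted over the list alone (median 0.43, adjusted p = 5.75e-05, adjusted p = 0.699 with an estimated correlation). Among ATP synthase genes 8 of 10 rose, 8 adjusted over the list alone (median 0.71, adjusted p = 0.000366, adjusted p = 0.296 with an estimated correlation). Of the carbon fixation and carboxysome genes, 10 of 14 rose, 10 adjusted over the list alone (median 0.74, adjusted p = 5.75e-05, adjusted p = 0.0841 with an estimated correlation). Among phosphate uptake genes 7 of 12 rose, 9 adjusted over the list alone (median 0.75, adjusted p = 0.000469, adjusted p = 0.320 with an estimated correlation). Within the high light inducible and photoprotection genes 4 of 6 rose, 4 adjusted over the list alone (median 0.48, adjusted p = 0.0372, adjusted p = 0.296 with an estimated correlation). Among sugar catabolism and glycogen genes 2 of 17 rose and 11 fell, 3 and 12 adjusted over the list alone (median -0.51, adjusted p = 0.000858, adjusted p = 0.152 with an estimated correlation). All hydrogenase genes fell (5 of 5, 5 adjusted over the list alone, median -0.95, adjusted p = 0.00646, adjusted p = 0.320 with an estimated correlation). Fits with a slide block gave medians of 0.59 for ribosomal proteins, 0.62 for the ATP synthase, 0.65 for carbon fixation, 0.62 for phosphate uptake, 0.61 for high light inducible proteins, -0.61 for sugar catabolism and -1.005 for the hydrogenase. With the scan session instead they were 0.62, 0.69, 0.67, 0.81, 0.57, -0.56 and -0.86 in that order. Within the slide and the session that held both strains the medians ran from 0.74 to 0.90, 0.73 to 0.79, 0.60 to 0.61, 0.66 to 0.73, 0.53 to 0.56, -0.84 to -0.63 and -1.22 to -0.87. The adjusted p of the high light inducible list was 0.0603 without CS replicate 3, 0.0506 without ΔsigBDE replicate 2 and 0.0809 without ΔsigBDE replicate 3, and its call also ended with normexp (0.0604). The sugar catabolism call ended with the brightest probe of each gene (0.0798). 1352 of 3259 genes were called (630 higher, 722 lower), 295 of them by at least 1, with 1228 (624 higher, 604 lower) and 1240 (676 higher, 564 lower) under the slide and the scan session as a block, of which 999 and 988 were among the same calls. With normexp background correction 586 genes were higher and 407 lower, and the median of all genes was 0.184 higher. 1207 of the called genes had arrays of the 2 strains that did not overlap, which holds for 42.2% of all genes tested and 5.71% by chance.

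What was changed when only SigB remained was read from ΔsigCDE against CS. The pentose phosphate genes tal (-2.17, SE 0.15, adjusted p = 6.80e-08), gnd (-1.82, SE 0.11) and opcA (-1.24, SE 0.22) fell, as did the polyhydroxybutyrate genes phaE (-1.47, SE 0.15) and phaC (-1.20, SE 0.24, adjusted p = 0.00273, and 0.0515 for its brightest probe). trxQ (-0.89) and the pilus genes pilC (-0.69) and pilT1 (-0.67) fell, and hliB (1.16, SE 0.20), the pilin gene pilA2 (0.91), atpG (0.62, adjusted p = 0.00682, and 0.0556 within the first session) and the phycobilisome linker gene cpcG2 (1.26, adjusted p = 0.00383, and 0.702 for its brightest probe) rose. Among genes named by locus tag, slr0364 (2.33) and slr0366 (2.20) rose and sll1675 (-1.83) and sll0584 (-1.73) fell.

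Within the sugar catabolism and glycogen genes 2 of 17 rose and 7 fell, 3 and 8 adjusted over the list alone (median -0.42, adjusted p = 0.000465, adjusted p = 0.0947 with an estimated correlation). Within the polyhydroxybutyrate genes 2 of 4 fell, 4 adjusted over the list alone (median -0.92, adjusted p = 0.000154, adjusted p = 0.0685 with an estimated correlation). Of the hydrogenase genes, 2 of 5 fell, 5 adjusted over the list alone (median -0.60, adjusted p = 0.000873, adjusted p = 0.199 with an estimated correlation). Within the ATP synthase genes 7 of 10 rose, 9 adjusted over the list alone (median 0.59, adjusted p = 1.27e-05, adjusted p = 0.122 with an estimated correlation). Among carbon fixation and carboxysome genes 3 of 14 rose, 9 adjusted over the list alone (median 0.33, adjusted p = 0.000259, adjusted p = 0.0947 with an estimated correlation). Within the phycobilisome genes 2 of 17 rose, 2 adjusted over the list alone (median 0.29, adjusted p = 0.00148, adjusted p = 0.616 with an estimated correlation). Among ribosomal protein genes 3 of 53 rose, 0 adjusted over the list alone (median 0.20, adjusted p = 0.000873, adjusted p = 0.689 with an estimated correlation). The slide block gave medians of -0.43 for sugar catabolism, -0.87 for polyhydroxybutyrate, -0.61 for the hydrogenase, 0.52 for the ATP synthase, 0.34 for carbon fixation, 0.45 for the phycobilisome and 0.10 for ribosomal proteins. A scan session block gave -0.40, -0.87, -0.61, 0.52, 0.35, 0.44 and 0.13 in that order. Within slides and the session that held both strains the medians ran from -0.42 to -0.39, -1.01 to -0.84, -0.67 to -0.60, 0.35 to 0.57, 0.32 to 0.34, 0.45 to 0.49 and 0.05 to 0.10. The ribosomal call ended without ΔsigCDE replicate 2 (adjusted p = 0.0749) and with quantile normalization (0.242) and the authors' values (0.288). With the replicate number as a block, photosystem I (median 0.37, 0 of 12 called) went from adjusted p = 0.0682 to 0.000334 and photosystem II (median 0.06, 1 of 26 called) from 0.329 to 0.0144. With an estimated correlation under this block the 2 lists were at 0.495 and 0.660. 367 of 3259 genes were called (152 higher, 215 lower), 70 of them by at least 1. Without ΔsigCDE replicate 1, 2 or 3 the count was 204, 195 or 212. With the slide as a block 506 genes were called (201 higher, 305 lower) and with the scan session 436 (164 higher, 272 lower), of which 344 and 337 were among the same calls. 359 of the called genes had arrays of the 2 strains that did not overlap, which holds for 26.5% of all genes tested and 5.71% by chance.

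Each triple strain was then set against ΔsigBCDE, from which it differed by design in the retained factor. The sigma probes and sll0685 showed other differences between these strains, so the comparisons do not isolate that factor. With SigE retained (ΔsigBCD), gnd was 4.32 higher on the log2 scale (SE 0.12, adjusted p = 4.27e-14), tal 3.90 (SE 0.16) and opcA 3.80 (SE 0.24), and pstS2 6.96 (SE 0.38). hoxY (1.48), hoxE (1.48) and the catalase gene katG (0.88) were higher, and ccmM (-1.80), ccmL (-1.66), atpF (-1.32) and hliB (-1.65) lower.

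Within the phosphate uptake genes 12 of 12 rose, 12 adjusted over the list alone (median 3.65, adjusted p = 7.10e-16, adjusted p = 0.0428 with an estimated correlation). Of the sugar catabolism and glycogen genes, 10 of 17 rose, 10 adjusted over the list alone (median 0.60, adjusted p = 0.000407, adjusted p = 0.127 with an estimated correlation). Among hydrogenase genes 5 of 5 rose, 5 adjusted over the list alone (median 0.98, adjusted p = 0.00751, adjusted p = 0.358 with an estimated correlation). Of the ATP synthase genes, 8 of 10 fell, 8 adjusted over the list alone (median -0.79, adjusted p = 0.00185, adjusted p = 0.358 with an estimated correlation). Within the carbon fixation and carboxysome genes 1 of 14 rose and 7 fell, 1 and 7 adjusted over the list alone (median -0.45, adjusted p = 0.00299, adjusted p = 0.277 with an estimated correlation). Within the ribosomal protein genes 3 of 53 rose and 29 fell, 4 and 30 adjusted over the list alone (median -0.54, adjusted p = 0.00333, adjusted p = 0.908 with an estimated correlation). The ribosomal call ended without ΔsigBCD replicate 3 (adjusted p = 0.0782) and with quantile normalization (0.0740). The 2 strains lay on the same 3 slides, so both blocks left the medians as they were, and within single slides they ran from 3.54 to 3.71, 0.36 to 0.72, 0.86 to 1.51, -1.04 to -0.58, -0.52 to -0.42 and -0.93 to -0.09 in the order given. 1532 of 3259 genes were called (770 higher, 762 lower), 472 of them by at least 1. With the slide and the scan session as a block 1741 (880 higher, 861 lower) and 1658 (830 higher, 828 lower) genes were called, 1524 and 1532 of them among the same calls. 1485 of the called genes had arrays of the 2 strains that did not overlap, which holds for 58.2% of all genes tested and 10% by chance.

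With SigD retained (ΔsigBCE), the flavodiiron genes flv2 (2.49, SE 0.62, adjusted p = 0.00285) and flv4 (2.10, SE 0.48) were higher than in ΔsigBCDE, and so were gpx1 (1.81), prxQ2 (1.42), hoxY (1.45), chlL (1.78), acsF1 (1.64) of aerobic chlorophyll synthesis, and psaD (1.36) of photosystem I. atpF (-1.64, SE 0.17), atpD (-1.47), ccmL (-1.59) and rpl3 (-1.49) were lower.

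Among ATP synthase genes 10 of 10 fell, 10 adjusted over the list alone (median -1.10, adjusted p = 4.43e-06, adjusted p = 0.487 with an estimated correlation). Of the ribosomal protein genes, 3 of 53 rose and 35 fell, 3 and 37 adjusted over the list alone (median -0.77, adjusted p = 1.25e-05, adjusted p = 0.663 with an estimated correlation). Of the carbon fixation and carboxysome genes, 1 of 14 rose and 7 fell, 1 and 7 adjusted over the list alone (median -0.44, adjusted p = 0.00634, adjusted p = 0.487 with an estimated correlation). Of the phosphate uptake genes, 7 of 12 fell, 8 adjusted over the list alone (median -0.57, adjusted p = 0.0141, adjusted p = 0.663 with an estimated correlation). Within the inorganic carbon uptake and flavodiiron genes 11 of 19 rose, 11 adjusted over the list alone (median 0.84, adjusted p = 0.00743, adjusted p = 0.663 with an estimated correlation). Of the NDH-1 genes, 8 of 15 rose, 8 adjusted over the list alone (median 0.47, adjusted p = 0.0314, adjusted p = 0.663 with an estimated correlation). Within the hydrogenase genes 4 of 5 rose, 4 adjusted over the list alone (median 0.98, adjusted p = 0.0446, adjusted p = 0.663 with an estimated correlation). The adjusted p of the NDH-1 list was 0.0960 without ΔsigBCDE replicate 1, 0.103 without ΔsigBCE replicate 2 and 0.0811 without ΔsigBCE replicate 3, and that of the hydrogenase list 0.0504 without CS replicate 4, 0.0571 without ΔsigBCDE replicate 1, 0.0586 without ΔsigBCDE replicate 3, 0.0893 without ΔsigBCE replicate 2 and 0.0655 without ΔsigBCE replicate 3. The hydrogenase call also ended with normexp (0.114) and the brightest probe of each gene (0.0693). With the slide as a block, list medians were -1.05 for the ATP synthase, -0.85 for ribosomal proteins, -0.45 for carbon fixation, -0.65 for phosphate uptake, 1.17 for carbon uptake, 0.51 for NDH-1 and 1.00 for the hydrogenase. The scan session as a block gave -1.04, -0.85, -0.43, -0.56, 0.99, 0.51 and 1.09 in that order. Within shared slides and the session they ran from -1.08 to -0.98, -0.82 to -0.69, -0.53 to -0.34, -0.80 to -0.63, 0.95 to 1.16, 0.50 to 0.69 and 0.92 to 1.15. 1736 of 3259 genes were called (901 higher, 835 lower), 553 of them by at least 1. With the slide and the scan session as a block 1920 (929 higher, 991 lower) and 1831 (911 higher, 920 lower) genes were called, 1638 and 1644 of them among the same calls. 1622 of the called genes had arrays of the 2 strains that did not overlap, which holds for 56.7% of all genes tested and 10% by chance.

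With SigC retained (ΔsigBDE), few genes differed from ΔsigBCDE. trxQ (0.95, SE 0.13, adjusted p = 0.000189) and katG (0.62, SE 0.09, adjusted p = 0.000508) were higher. The pilin genes pilA2 (-1.31, SE 0.20) and pilA4 (-1.30, SE 0.15, adjusted p = 3.57e-05, and 0.0630 with normexp) and the ATP synthase genes atpF (-0.83) and atpG (-0.75) were lower. Among genes named by locus tag, slr0376 (2.29) and sll1675 (2.13) were higher and slr0364 (-4.13) and slr0366 (-3.31) lower. Within the ATP synthase genes 5 of 10 fell, 9 adjusted over the list alone (median -0.54, adjusted p = 2.88e-06, adjusted p = 0.468 with an estimated correlation). Within the antioxidant genes 2 of 16 rose, 2 adjusted over the list alone (median 0.22, adjusted p = 0.0310, adjusted p = 0.750 with an estimated correlation). Among ribosomal protein genes 1 of 53 rose, 0 adjusted over the list alone (median -0.30, adjusted p = 0.000594, adjusted p = 0.958 with an estimated correlation). The single ribosomal call went against the median. The adjusted p of the antioxidant list was 0.158 without ΔsigBCDE replicate 1, 0.114 without ΔsigBDE replicate 2 and 0.222 without ΔsigBDE replicate 3, and that of the ribosomal list 0.0645 without ΔsigBCDE replicate 3 and 0.687 without ΔsigBDE replicate 1. The antioxidant call also ended with normexp (0.184), quantile normalization (0.0980), the authors' values (0.0685) and the brightest probe of each gene (0.0921) and the ribosomal call with quantile normalization (0.105) and the authors' values (0.0706). Both blocks left the medians as they were, and within single slides and the session they ran from -0.62 to -0.47 for the ATP synthase, 0.08 to 0.29 for antioxidant enzymes and -0.41 to -0.29 for ribosomal proteins. With the replicate number as a block photosystem I (median 0.46) went from adjusted p = 0.0776 to 0.0274, and to 0.936 with an estimated correlation under this block.

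Against ΔsigBCDE, in ΔsigBDE 277 of 3259 genes were called (192 higher, 85 lower), 70 of them by at least 1. With the slide and the scan session as a block 515 (294 higher, 221 lower) and 422 (259 higher, 163 lower) genes were called, 277 and 277 of them among the same calls. The count was 128 without ΔsigBCDE replicate 3 and 552, 131 and 152 without ΔsigBDE replicates 1, 2 and 3. The share of higher calls, 69.3%, was 48.8% after median scaling (165 higher, 173 lower), 57.4% with the authors' values (257 higher, 191 lower) and 80.4% with normexp (246 higher, 60 lower), which raised the median of all genes by 0.198. 274 of the called genes had arrays of the 2 strains that did not overlap, which holds for 28.1% of all genes tested and 10% by chance.

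With SigB retained (ΔsigCDE), sigA (2.22, SE 0.25, adjusted p = 4.54e-06) and the photosystem I genes psaD (1.62, SE 0.29), psaF (1.35) and psaL (1.29) were higher than in ΔsigBCDE. opcA (1.80), gpx1 (1.51), the peroxiredoxin gene prx1cys (1.18) and the haem oxygenase gene ho1 (1.29) were higher too. rpl15 (-1.29), atpF (-1.22), ccmL (-1.21), ccmM (-1.21), pilA4 (-1.96) and nblA1 (-1.34) were lower.

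Within the ribosomal protein genes 2 of 53 rose and 31 fell, 3 and 33 adjusted over the list alone (median -0.65, adjusted p = 0.000480, adjusted p = 0.568 with an estimated correlation). Of the ATP synthase genes, 9 of 10 fell, 10 adjusted over the list alone (median -0.67, adjusted p = 0.000480, adjusted p = 0.545 with an estimated correlation). Within the photosystem I genes 8 of 12 rose, 8 adjusted over the list alone (median 0.86, adjusted p = 0.0202, adjusted p = 0.568 with an estimated correlation). Among carbon fixation and carboxysome genes 1 of 14 rose and 8 fell, 1 and 8 adjusted over the list alone (median -0.44, adjusted p = 0.0146, adjusted p = 0.545 with an estimated correlation). Among phosphate uptake genes 5 of 12 fell, 5 adjusted over the list alone (median -0.50, adjusted p = 0.0160, adjusted p = 0.545 with an estimated correlation). The photosystem I call ended without ΔsigBCDE replicate 1 (adjusted p = 0.125) and with the authors' values (0.0521). No slide or session held both strains. Fits with a slide block gave medians of -0.89 for ribosomal proteins, -0.58 for the ATP synthase, 1.50 for photosystem I, -0.35 for carbon fixation and -0.47 for phosphate uptake. With the scan session instead they were -0.86, -0.59, 1.49, -0.37 and -0.49 in that order. The carbon fixation and phosphate uptake lists were not called with the slide (adjusted p = 0.131 and 0.125) or the scan session as a block (0.148 and 0.0858). 1494 of 3259 genes were called (821 higher, 673 lower), 436 of them by at least 1. With the slide and the scan session as a block 1295 (621 higher, 674 lower) and 1337 (619 higher, 718 lower) genes were called, 1020 and 1036 of them among the same calls. 1467 of the called genes had arrays of the 2 strains that did not overlap, which holds for 59.0% of all genes tested and 10% by chance.

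Among the 4 triple strains, 1830 of 3259 genes differed in the F test, 665 of them with strain means at least 1 apart on the log2 scale, and 1944 and 1916 genes were called with the slide and the scan session as a block. The smallest p belonged to sll0685 (adjusted p = 1.48e-15), sphX for a phosphate-binding protein (1.65e-14) and gnd (1.68e-13), followed by pstA2, pstC1, pstB1b, sll2013, pstA1, pstB1 and tal. The sphX mean was 1.67 in ΔsigBCD and -2.23, -1.73 and -2.34 in ΔsigBCE, ΔsigBDE and ΔsigCDE, and the gnd means were 2.17, -1.17, -1.92 and -0.97 in that order. sll2013, the locus tag next in number after sigD, stood at -0.24 in ΔsigBCE and at -3.70, -3.22 and -1.70 in ΔsigBCD, ΔsigBDE and ΔsigCDE. Among the genes that differed, 1166 separated ΔsigBCE from ΔsigBDE, 1041 ΔsigBCD from ΔsigBDE, 892 ΔsigBDE from ΔsigCDE, 856 ΔsigBCD from ΔsigBCE, 800 ΔsigBCD from ΔsigCDE and 380 ΔsigBCE from ΔsigCDE.

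Genes changed in the same direction in all 5 strains numbered 31, 13 higher and 18 lower, and 25 and 38 with the slide and the scan session as a block. Besides sigE, the largest mean changes included ssr2016 (2.86, between 1.38 and 4.71), pilA2 (1.61, between 0.79 and 2.87) and pilA1 (1.56, between 1.00 and 2.50). The pilA1 call in ΔsigCDE ended without ΔsigCDE replicate 1 (adjusted p = 0.0530), and both pilin calls in ΔsigBDE ended with the slide (adjusted p = 0.103 for pilA1 and 0.0799 for pilA2) or the scan session as a block (0.118 and 0.0748) and within the second session (0.264 and 0.223). The 5 comparisons shared the CS arrays. Simulated strains without change gave 0 such genes, independent lists of these sizes would give 0.209, fits with 2 of the controls gave 10 to 21, and fits with the controls split between strains 6 to 11. ΔsigBCDE and ΔsigBDE had the highest correlation of fold changes across genes (r = 0.876, 0.428 simulated without change, 0.715 to 0.850 with the controls split), with a covariance of 0.433 against 0.0176 simulated. They shared 552 higher and 623 lower calls, against 168 and 213 for independent lists, and 5 genes went opposite ways. For ΔsigBCD and ΔsigBCE r was 0.201, with 0.431 simulated, 0.0245 to 0.207 with the controls split and a covariance of 0.0523 against 0.0177.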

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

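The tests of the scan session slopes, of the phosphate uptake genes and of the sigC probe were chosen after the results were seen. In the 4 CS arrays, 5 of the 84 genes named in the report had an array far from the others by Dixon's ratio of the gap to the range. These were petJ in replicate 4 (ratio 0.901, value -4.20 against -3.26 to -3.16), phaA in replicate 1 (ratio 0.834, value -1.31 against -0.96 to -0.89), ccmK4 in replicate 3 (ratio 0.854, value -0.02 against -0.37 to -0.32), psaD in replicate 4 (ratio 0.831, value 4.87 against 4.00 to 4.15) and prx1cys in replicate 4 (ratio 0.914, value 3.33 against 2.92 to 2.96). Chance gives about 1 in 20 such groups. No biological explanation was tested for these values, and groups of 3 arrays were not tested in this way.

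All arrays of ΔsigBCDE, ΔsigBCD and ΔsigBDE were read in a scan session with a single CS array, so a difference between sessions might pass for a difference between strains. If it did, control array 4 would differ from control arrays 1 to 3 along the same genes. The slope of that difference on the strain difference over called genes was -0.0513 for ΔsigBCDE, 0.0893 for ΔsigBCD and 0.00471 for ΔsigBDE, which argues against the session as the whole of the change. A session effect on single genes stays open, since the blocked fits left out some calls.

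The phosphate uptake genes were raised in ΔsigBCD. A single culture or array that stood apart was argued against by the lowest of the 3 array medians over the 12 genes, 3.93 above the control mean. The absence of SigB, SigC and SigD alone was argued against by ΔsigBCDE, which lacks them too and lay 3.65 below ΔsigBCD in the median of these genes. A second change in this strain at sll0685, not well above background on 3 of its arrays, may be a source of the rise. The arrays cannot tell it apart from an effect of SigE acting alone. The biological explanation that SigE without the other factors raises these genes stays open as untested.

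The retained sigC of ΔsigBDE had a lower value than in CS. A wrong label, with RNA of ΔsigBCDE on the ΔsigBDE arrays, was argued against by the sigC probe that was not well above background in ΔsigBCDE, which was 5.52 higher in ΔsigBDE on the log2 scale. Its 3 probes changed unevenly in ΔsigBDE, by -1.16, -0.66 and -0.05 at positions 24, 343 and 918, and the reason was not tested. A biological fall of sigC in ΔsigBDE stays open as untested.

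Other splits of the arrays into groups of the same sizes were planned before the data were examined. Of the 35 splits for each strain against CS, 1, the real one, reached the count of called genes. That is the smallest share 35 splits can give, and the arrays were not interchangeable. Control arrays 1 to 3 were read in another session than ΔsigBCDE, ΔsigBCD and ΔsigBDE, and ΔsigCDE was paired with CS by slide. The splits therefore cannot exclude chance. The real counts were 1829, 941, 410, 1352 and 367 for ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE, and the highest of the other splits 1169, 642, 218, 623 and 69. Against ΔsigBCDE the 10 splits are too few for a share under 0.05, with 1 as large as the real one. The real counts there were 1532, 1736, 277 and 1494 for ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE, and the highest others 0, 0, 220 and 1. Where replicate numbers pair the arrays, the other splits that part all 3 pairs gave at most 39 genes over 7 splits for ΔsigCDE against CS and 0 over 3 for ΔsigBDE against ΔsigBCDE, and those that part fewer pairs at most 69 and 220. Of 100 regroupings, 1, the real one, was as large as the real count for the F test (1830, highest other 1308), for the genes changed in all 5 strains (31, highest other 0) and for the inactivated sigma genes (16, highest other 1). For the F test this argues against chance as the whole of the count. For the other counts the regrouping decides little, since regrouping all arrays asks only whether any strains differ. It does not ask whether strains share changes beyond their common controls, and the sigma genes were inactivated by design. For the number of list calls, 60, 24 of 100 regroupings were as large and the highest other was 78, so chance could not be excluded.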

How the results depend on the processing

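The scan session as a block and the fits within sessions were chosen after the results were seen, and the other alternatives before the data were examined. Leaving out each array gave 1616 to 1777 called genes for ΔsigBCDE, 731 to 995 for ΔsigBCD, 294 to 365 for ΔsigBCE, 1136 to 1297 for ΔsigBDE and 195 to 297 for ΔsigCDE against CS. Against ΔsigBCDE it gave 1272 to 1371 for ΔsigBCD, 1535 to 1674 for ΔsigBCE, 128 to 552 for ΔsigBDE and 1237 to 1348 for ΔsigCDE. The F test ranged from 1618 to 1841, the genes changed in all 5 strains from 21 to 40, list calls from 55 to 68 and inactivated sigma genes from 15 to 16.

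Counts moved by more than 1.5 times as follows, and the cause was not tested except where the construction shows it. Requiring a change of at least 1 is stricter and left 637, 221, 73, 295 and 70 genes for ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE against CS, 472, 553, 70 and 436 for ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE against ΔsigBCDE, 665 in the F test and 2 in all 5 strains. normexp gave 268 for ΔsigBCE and 217 for ΔsigCDE against CS and 14 in all 5. The brightest probe gave 225 for ΔsigCDE against CS, 20 in all 5 and 6 sigma genes. For ΔsigBDE against ΔsigBCDE, quantile normalization gave 440, the authors' values 448, the slide as a fixed block 515 and as a random block 463, and the scan session as a block 422. The scan session as a block gave 626 for ΔsigBCE against CS. With fewer arrays, fits of only the strains compared gave 218 for ΔsigBCE against CS, 124 for ΔsigBDE against ΔsigBCDE and 15 in all 5, the first session alone 269 for ΔsigBCE against CS, and the second 421, 66 and 828 for ΔsigBCD, ΔsigBCE and ΔsigBDE against CS. There a lone CS array was assumed to vary like the others. An estimated correlation left 4 list calls and fry gave 93. By less than 1.5 times, the slide and the scan session as a block moved the list calls to 75 and 73.

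Of 4855 alternative values of 210 gene changes, 4635 held, 114 lost or, in 7, gained the call, and 6 reversed. Within single slides 179 held by moving less than the residual SD and 100 moved more. Signs of uncalled values were not compared. Reversed was sigD with its brightest probe, at its start. It was 0.92 in ΔsigBCDE, 0.81 in ΔsigBCD, 1.06 in ΔsigBDE and 0.16 in ΔsigCDE against CS. Against ΔsigBCDE it was -0.18 in ΔsigBCE and -0.76 in ΔsigCDE. The cause was not tested. No scaling turned the sign of a called list. Median scaling turned the balance of higher and lower calls in ΔsigBCDE and ΔsigBCE against CS and in every comparison with ΔsigBCDE, with 744 higher and 803 lower in ΔsigCDE.

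With the replicate number as a block, 1827, 1016, 373, 1338 and 298 genes were called for ΔsigBCDE, ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE against CS, 1593, 1816, 312 and 1573 for ΔsigBCD, ΔsigBCE, ΔsigBDE and ΔsigCDE against ΔsigBCDE, 1948 in the F test and 29 in all 5 strains, with 66 list calls and 15 sigma genes. In the pair ΔsigCDE and CS and the pair ΔsigBDE and ΔsigBCDE this block moved the counts by less than 1.5 times. In these 2 comparisons it changed no list call other than those of photosystem I and II given in the report, and no call of a gene named there. Over all comparisons, 59 of the 60 list calls held with it, and the calls of sigH in ΔsigBCDE (0.123) and sigB in ΔsigBCE (0.0609) ended. Other pairs share a number, and those of ΔsigBCD and ΔsigBCDE a slide. Correlations were -0.532 to 0.373, and at most 5 of 6 arrays correlated best with their own number. normexp raised the median of all genes by 0.184 in ΔsigBDE against CS and, against ΔsigBCDE, 0.139 in ΔsigBCD and 0.198 in ΔsigBDE. Signal near background limits folds of dim probes to bounds.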

Other observations

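The tests of retained factors were planned before the data were examined, and their blocked fits and the session slope for SigB were chosen after the results were seen. In the main fit, some gene groups had no list call in any of the 9 comparisons. Their medians ran from -0.24 to 0.35 for photosystem II (smallest adjusted p = 0.0954), -0.18 to 0.29 for cytochrome b6f and soluble carriers (0.542), -0.18 to 0.30 for carotenoid and tocopherol synthesis (0.329), -0.37 to 0.39 for FtsH and Deg proteases (0.186), -0.38 to 0.35 for nitrogen assimilation (0.320), -0.39 to 0.13 for glucosylglycerol (0.145) and -0.49 to 0.52 for RNA polymerase and the other sigma factors (0.291). Members moved in both directions. Up to 14 of 26 photosystem II genes and up to 8 of 19 nitrogen genes were called in a comparison.

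If a factor drives genes, those changed in the same direction in the 3 triple strains without it may differ between the strain that keeps it and ΔsigBCDE in the direction that undoes the change. For SigE this held for 58 of 81 genes (71.6%), with 3 further away. Of all genes 47.0% were called between these 2 strains. In ΔsigBCD 30 of the 58 were not called against CS. For SigD it held for 97 of 115 genes (84.3%, 3 further away, 53.3% of all genes, 63 not called against CS), and for SigB for 69 of 92 genes (75%, 3 further away, 45.8% of all genes, 50 not called). For SigC it held for 26 of 54 genes (48.1%, 1 further away, 8.50% of all genes, 11 not called). SigC had the largest excess over all genes but stayed under the preset 50%, which left it undecided. With the slide and the scan session as a block, in the choice of the genes and the comparison, the shares were 63.5 and 57.6% for SigC, 80.6 and 75.9% for SigE, 88.2 and 87.7% for SigD and 87.5 and 87.1% for SigB. The blocks for SigB rest largely on the single CS array of the second session, whose error enters both steps. The strains without SigB lay mostly in that session and ΔsigCDE in the other, so a difference between sessions might pass for SigB dependence. Control array 4 would then differ from arrays 1 to 3 along the same genes, but the slope of that difference on ΔsigBCDE minus ΔsigCDE over the 92 genes was 0.0186. This argues against the session as the whole of the pattern. SigB, SigD and SigE passed 50% without a block, SigC only with one. For the first 3, 50% lay near the 45.8, 53.3 and 47.0% of all genes called in either direction. Of the genes of SigB, SigC, SigD and SigE, 88, 50, 110 and 74 also changed in ΔsigBCDE, which may raise their shares. 33 of each also changed in the strain that keeps the factor. The shares therefore do not decide dependence on it. A milder response of that strain, or another difference from ΔsigBCDE, would give the same. The comparisons also share the CS and ΔsigBCDE arrays, so dependence remains a hypothesis.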
